A study of Mus musculus with 5 samples.

How the data were processed

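Gene expression was measured in endothelial cells sorted from the thymus of female C57BL/6J mice, on single-colour Affymetrix MOE 430 A 2.0 arrays. Per the labels' protocols, thymus cells were first depleted of CD45-positive blood cells on magnetic columns. Cells negative for CD45 and EpCAM and positive for VE-cadherin were then collected by flow sorting. Each array held RNA of cells pooled from several mice, converted to biotin-labelled cRNA with a 3' in vitro transcription kit. The labels gave 3 arrays of untreated mice (day 0) and 2 arrays of mice taken 4 days after sublethal total body irradiation at 550 cGy, without hematopoietic rescue.

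The deposited values were 1 log2 value per probe set and array. The authors made the log2 values with GCRMA, per the submitters' processing notes; its version, and whether all 5 arrays were normalized together, are not given in the sources used here. GCRMA corrects background with the probe sequences, normalizes the arrays it is run on to a common distribution and summarizes the probes of a set. That normalization hides any change shared by most genes, and its background correction spreads out low values. The table carried no detection calls, so fold changes of genes near the background rest on background values. The log scale was read from the values, which lay between 1.57 and 14.4 with array medians of 5.26 to 5.30. No label gave a batch, date or litter.

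The table held 22690 probe sets, of which 64 were control probe sets. The platform annotation named 1 gene symbol for 20380 probe sets, several for 691 and none for 1555. Symbols were checked through the Entrez identifiers of the RefSeq gene table of the mouse reference genome. Of the 20380 probe sets, 20351 matched and 29 did not, and 0 symbols changed. No genome coordinates are given because the array's build was not named. Probe sets with several symbols or none took no part in the gene counts. Those past the level filter were examined separately by identifier.

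A probe set entered the tests if its log2 value was above 4 on at least 2 arrays, which left 15065 probe sets. Of these, 13868 had 1 symbol. Each gene was represented by the probe set with the highest mean over the 5 arrays, giving 8940 genes. The groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, at default settings, two-sided, with no covariate. The log2 change is day 4 minus day 0, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Values per group are given as mean ± SD over arrays, and errors of log2 changes as standard errors (SE). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The precision is limited by the number of arrays, which left 3 residual degrees of freedom and 3.29 prior degrees of freedom from all genes. Because each array was a pool of cells of several mice, p-values measure the spread between these pools, which may be partly technical.

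Gene lists were written from textbook knowledge: 23 on biological processes and vessel types and 8 on markers of other cells of the thymus. Each list with at least 5 measured members was tested with limma camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over 30 lists. Camera with an estimated correlation and fry were the alternatives. With an estimated correlation, camera tests each list at the 3 residual degrees of freedom, so few lists can pass even where members are uncorrelated. Calls of single members are given over all genes tested and adjusted over the list alone. Another 6 lists were added after the values were seen. Their p-values were adjusted only among those of them with at least 5 measured members.

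Genes were named by a fixed rule. It took the 10 largest rises and the 10 largest falls among called genes whose day 4 arrays all lay on one side of the day 0 arrays. It took, of each list, the 2 called members with the largest rise and the 2 with the largest fall. It also took, whatever their values, Bmp4, Kitl, Dll4, Il33, Cdkn1a, Mdm2, Nod2, Rac1 and Gpr39 for the study question, and Cdh5, Pecam1, Epcam and Ptprc as markers of the sort. Nod2 and Gpr39 were not named by a probe set with 1 symbol and are not analysed here. The rule gave 57 genes, 48 of them called. The groups, tests, lists, naming rule and most alternatives were chosen before the data were examined.

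The alternatives were quantile normalization or median centring of the arrays, no level filter or one at 6, the mean of a gene's probe sets, and eBayes with an intensity trend and robust fitting. Further ones were array weights, the replicate number as a block, other thresholds, all probe sets in place of genes, and leaving out each array in turn. A covariate for signal of other cells was added after the values were seen. It was the mean of the thymocyte and myeloid list levels of each array. These lists moved in opposite directions between the groups, so their mean partly cancels their shifts.

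The comparison was tested on simulated data for the 8940 genes with 2 and 3 arrays, 20 times, with 200 changed genes each. It recovered 94.9% of genes changed by 1 on the log2 scale and 99.4% of those changed by 2. Of the calls, 6.29% were false, and without any change a mean of 0.05 genes was called. A shifted list was found in 20 of 20 simulations and an unshifted list in 0. The simulated genes varied independently, and every member of the shifted list was moved. Their noise was normal, with the variances that eBayes estimated. Effects shared by the genes of an array were not simulated, so the rates of recovery and of false calls describe an ideal case. Estimated correlations in the data were 0.34 for mitosis, 0.43 for thymocytes and 0.57 for myeloid cells. The simulation therefore gives no rate of false list calls for such lists.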

Results

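The data set held 5 arrays of sorted thymic endothelial cells, the cells that line the blood vessels of the thymus. Of these, 3 came from untreated mice and 2 from mice 4 days after a sublethal 550 cGy dose of total body irradiation, which depletes thymocytes and shrinks the organ. The labels named the day 4 cells as CD45-negative thymic stromal cells and the untreated ones as thymic endothelial cells, while the protocol gave the same endothelial sort for both. Cdh5, which encodes the VE-cadherin used in the sort, stood at 11.57 ± 0.065 (SD, n = 3) at day 0 and 11.39 ± 0.0086 (SD, n = 2) at day 4. Its log2 change of -0.18 did not pass the limma test (adjusted p = 0.307). Neither did those of Pecam1, an endothelial adhesion molecule (0.14, adjusted p = 0.61), or of Epcam, the epithelial marker the sort excluded (-0.48, adjusted p = 0.56). Ptprc, which encodes CD45, differed by 0.0049 (adjusted p = 0.992), by -0.015 after quantile normalization and by -0.020 after median centring. Ptprc had a mean of 6.52 at day 0 and 6.53 at day 4, and Epcam of 6.90 and 6.42. Both lay above the level filter on every array, so these values do not show that the excluded cells were absent. Between 64.8% and 65.4% of probe sets lay above a log2 value of 4 on each array. The 3' minus 5' log2 signal of control probe sets, a sign of RNA quality, lay lower on both day 4 arrays. For actin it was 1.59, 1.65 and 1.43 at day 0 against 1.35 and 1.39 at day 4. For Gapdh it was 0.96, 0.90 and 0.93 against 0.82 and 0.83. Across genes, arrays correlated with r of 0.990 to 0.992 within day 0, 0.984 within day 4 and 0.966 to 0.978 between the groups. Genes are not independent replicates, so these correlations only describe the arrays. The first principal component, with 60.7% of the variance, separated the groups, and the second, with 19.1%, separated the 2 day 4 arrays.

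The comparison asked how thymic endothelial cells differ in expression 4 days after irradiation. Of 31 measured targets of the DNA damage regulator p53, 12 rose at day 4, Phlda3 and Ccng1 among them (for the list, adjusted p = 0.109 with an estimated correlation). Single genes known from macrophages, such as Cd163, rose as well. Of 11 thymocyte genes 7 fell, such as Rag1, and of 22 mitosis genes 11 fell, such as Mki67, while Ckap2 rose. For each of these last lists, adjusted p = 0.460 with an estimated correlation. Of 8940 genes tested, 255 passed the limma threshold, 134 higher and 121 lower at day 4. An unadjusted p under 0.05 was found for 1896 genes. At least 2-fold changes were found for 68 of the higher and 61 of the lower genes. On all 255, the day 4 arrays lay apart from the day 0 arrays, which held for 41.1% of all tested genes against 20% by chance. Of the lower genes, 42 had a day 4 mean under the level filter, and of the higher ones 16 had such a day 0 mean. Another probe set past the filter existed for 70 of the called genes and went the opposite way for 4, which are Rad51ap1, Tubb4b, Cbx1 and Vmp1, named after their values were seen. The count rested on single arrays: without day 4 replicate 1 it was 10 genes, without day 0 replicate 3 it was 40, without day 0 replicate 1 it was 153 and without day 0 replicate 2 it was 162. Array weights gave 86 genes and the covariate for other cells 102, while an intensity trend with robust fitting gave 418.

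The largest rises were those of Cd163, the hemoglobin scavenger receptor of macrophages, Cd5l, Apoc1, Vsig4, Gm6958, Ccl8, Ms4a6d, F13a1, Phlda3 and Fcgr1. Cd163 rose from 3.33 ± 0.47 (SD, n = 3) to 6.22 ± 0.30 (SD, n = 2), a 7.43-fold change (limma adjusted p = 0.0113). Cd5l, a protein secreted by macrophages, rose by 2.74 ± 0.43 (SE) and Apoc1, an apolipoprotein, by 2.72 ± 0.26. Vsig4, a complement receptor of tissue macrophages, rose by 2.69 ± 0.42 and the Fc receptor gene Fcgr1 by 2.37 ± 0.30. The chemokine gene Ccl8 rose by 2.60, Gm6958 by 2.61, Ms4a6d by 2.50 and F13a1, a coagulation factor subunit, by 2.45. The day 0 means of Cd163, Vsig4 and Fcgr1 lay under the level filter, so their folds rest on background values.

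The largest falls included genes of developing T cells. Rag1, which cuts antigen receptor genes during recombination, fell from 7.11 ± 0.55 (SD, n = 3) to 3.10 ± 0.056 (SD, n = 2), with a limma adjusted p of 0.00566. The log2 change was -3.04 for Satb1, a chromatin organizer of thymocytes, and -2.95 for the thymus homing receptor gene Ccr9. It was -3.26 for the T cell receptor segment Trbv1 and -2.83 for the transcription factor gene Myb. Csn2, which encodes the milk protein beta-casein, changed by -3.66, Calcb by -3.24, Wfdc18 by -2.70 and 2210407C18Rik by -3.31. S100a8, a calcium-binding protein of neutrophils, fell by 2.93. The adjusted p of these 10 genes lay between 0.00566 and 0.0244. Of the 10, 5 had a day 4 mean under the level filter.

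**Figure D1:**
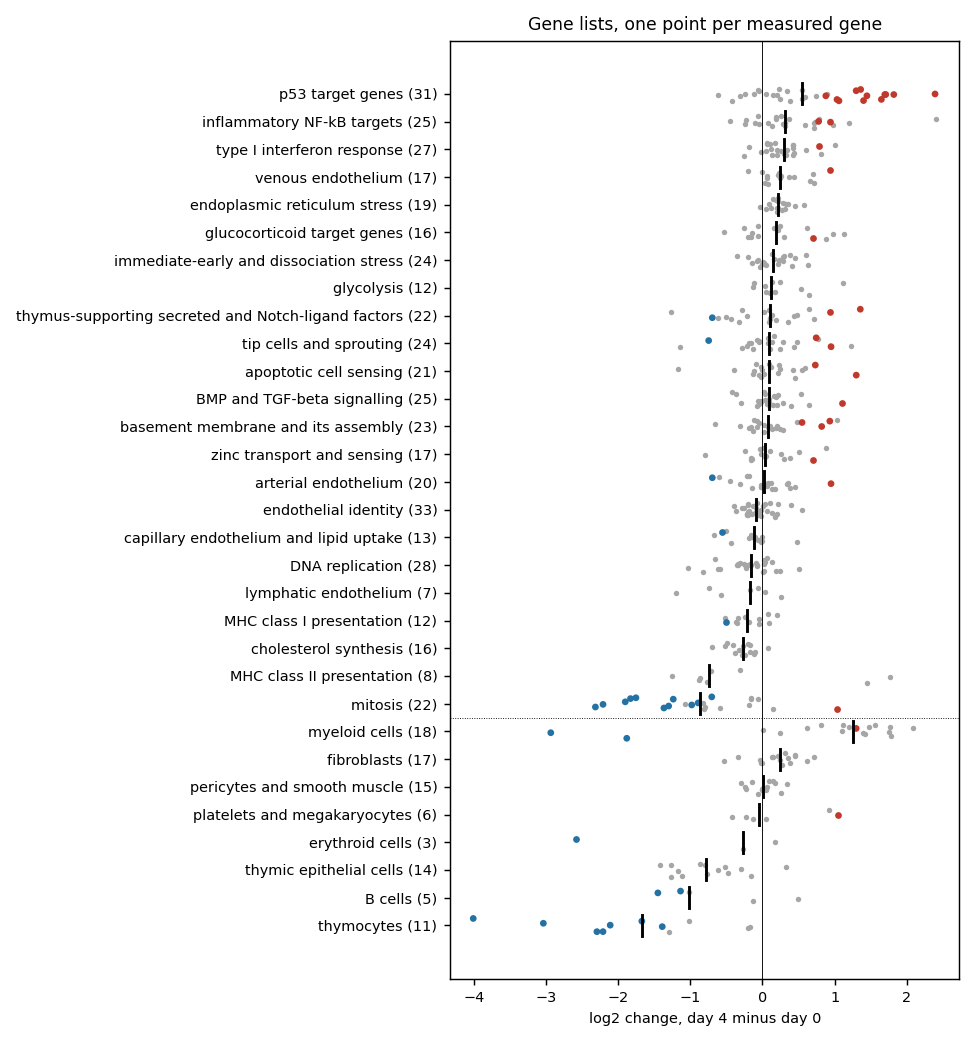
Log2 change at day 4 against day 0 of each measured member of the 31 gene lists, with the number of members in parentheses. Each point is 1 gene, coloured red (higher) or blue (lower) where it passed the threshold, and the bar is the list's median, which was 0.55 for p53 target genes, -0.86 for mitosis, 1.25 for myeloid cells and -1.67 for thymocytes.

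The list of p53 target genes, which arrest the cycle, repair DNA or promote cell death after damage, had 12 of 31 measured members higher and 0 lower, and adjusted over the list alone 18 were higher and 1 lower. Phlda3, an inhibitor of Akt signalling, rose from 6.35 ± 0.10 (SD, n = 3) to 8.74 ± 0.0068 (SD, n = 2), a 5.25-fold change (limma adjusted p = 0.00107). Ccng1, which encodes cyclin G1, rose 3.53-fold from 8.08 ± 0.089 to 9.90 ± 0.12. The cell cycle inhibitor gene Cdkn1a rose 2.05-fold from an already high 11.75 ± 0.065 to 12.78 ± 0.0017. Mdm2, whose product degrades p53, rose 2.46-fold (adjusted p = 0.0325). The list's median change was 0.55 (limma camera adjusted p = 8.51e-12; adjusted p = 0.109 with an estimated correlation). With fry, the adjusted p was 0.00169. Without day 4 replicate 1, 4 members passed the threshold. With the covariate for other cells 8 did, at a list median of 0.59.

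Of the 22 measured members of the mitosis list, 11 were lower and 1 higher at day 4, and adjusted over the list alone 15 were lower and 1 higher. Mki67, a marker of cycling cells, fell from 6.70 ± 0.42 (SD, n = 3) to 4.38 ± 0.27 (SD, n = 2), and Ube2c, which drives mitotic protein breakdown, fell by 2.21 on the log2 scale. Ckap2, which encodes a spindle protein, rose by 1.04 ± 0.10 (SE), with a limma adjusted p of 0.0118. The median change was -0.86 (limma camera adjusted p = 1.20e-09; adjusted p = 0.460 with an estimated correlation). Lower calls numbered 1 without day 4 replicate 1 and 1 without day 0 replicate 3, 5 without day 4 replicate 2, 7 without day 0 replicate 1 and 4 with the covariate for other cells, at a list median of -0.67. Of 28 members of the DNA replication list, 0 passed the limma threshold and 9 had an unadjusted p under 0.05, and adjusted over the list alone 4 were lower. Its median was -0.16 (camera adjusted p = 0.0295; adjusted p = 0.512 with an estimated correlation). That call was lost without day 0 replicate 1 (median -0.13, adjusted p = 0.109), without day 4 replicate 2 (-0.14, adjusted p = 0.505) and with the covariate (-0.088, adjusted p = 0.446). The mean level of the thymocyte list was 6.29, 5.57 and 6.10 on the day 0 arrays and 4.27 and 4.16 on the day 4 arrays.

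**Figure D2:**
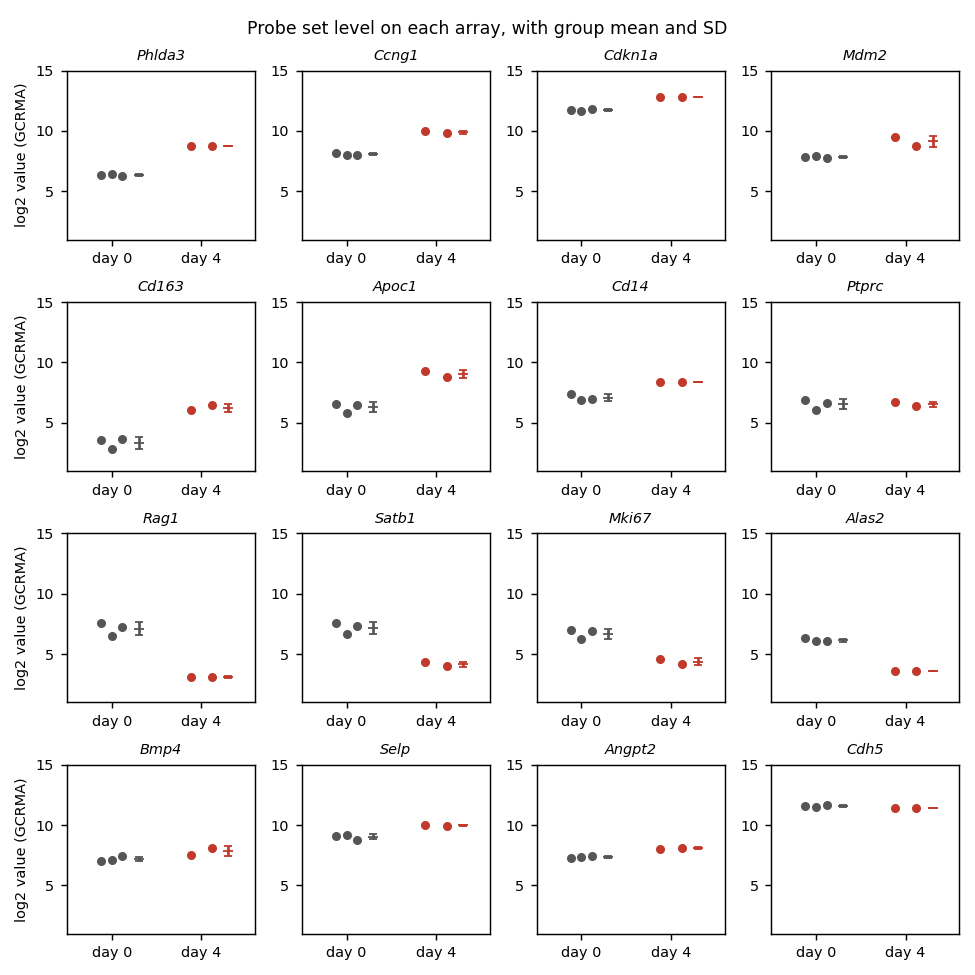
GCRMA log2 value (vertical axis) of 16 named genes on each of the 3 day 0 and 2 day 4 arrays, as points, with the group mean and SD beside them. Phlda3, Ccng1, Cdkn1a and Cd163 lie higher at day 4, Rag1, Satb1, Mki67 and Alas2 lower, and Cdh5 differed by -0.18.

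Lists of markers of other cells had medians of both signs. Of 11 measured thymocyte genes, 7 were lower and 0 higher, and adjusted over the list alone 9 were lower. Rag1 and Satb1 led these, and the list's median was -1.67 (limma camera adjusted p = 5.13e-09; adjusted p = 0.460 with an estimated correlation). Without day 4 replicate 1 no thymocyte gene passed, and without day 0 replicate 3 only 1 did. There were 3 without day 4 replicate 2, 4 without day 0 replicate 1 and 4 with the covariate for other cells, at a list median of -1.41. Of 18 myeloid genes, 1 was higher and 2 were lower, while adjusted over the list alone 13 were higher and 2 lower. Cd14, the co-receptor for bacterial lipopolysaccharide, rose by 1.30 ± 0.17 (SE), and S100a8 and S100a9, both abundant in neutrophils, changed by -2.93 and -1.88. The myeloid median was 1.25 (camera adjusted p = 5.59e-06; adjusted p = 0.506 with an estimated correlation). Higher myeloid calls numbered 11 without day 0 replicate 1, 2 without day 0 replicate 2 and 0 without any other single array. They numbered 12 with the covariate for other cells, at a list median of 1.66. The covariate is made of the thymocyte and myeloid lists themselves, so its fit is no check of either list. Of 5 B cell genes, Cd79b (-1.14) and Ms4a1 (-1.45) were lower, and adjusted over the list alone 2 were lower and 1 higher (median -1.01, camera adjusted p = 0.106). Cd79b went from a mean of 4.65 to 3.51 and Ms4a1 from 4.42 to 2.97. Both day 4 means lay under the level filter, so these changes rest on background values. The B cell median was -0.52 without day 4 replicate 1, and 0 B cell genes passed without that array or day 0 replicate 3, and 1 without day 0 replicate 1 or day 4 replicate 2. Of the erythroid list 3 members were measured, too few for a list test (median -0.27), and 1 was lower over all genes and adjusted over the list alone. That gene was Alas2, the heme synthesis enzyme of red cell precursors, which fell from 6.15 ± 0.14 (SD, n = 3) to 3.57 ± 0.0095 (SD, n = 2), with a limma adjusted p of 0.00107.

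Of the 14 measured thymic epithelial genes, 0 passed the limma threshold over all genes, 6 had an unadjusted p under 0.05, and 4 were lower adjusted over the list alone. Their median was -0.78 (camera adjusted p = 0.00161; adjusted p = 0.506 with an estimated correlation), and 13 of the 14 values were below 0. The shift rested on day 4 replicate 2, without which the median was -0.28 (camera adjusted p = 0.422), against -1.32 without day 4 replicate 1. With the covariate for other cells it was -0.19 (camera adjusted p = 0.233). Of 17 fibroblast genes 0 passed (6 at an unadjusted limma p under 0.05), and adjusted over the list alone 2 were higher. Their median was 0.24 (camera adjusted p = 0.0224; adjusted p = 0.523 with an estimated correlation). The fibroblast median was -0.011 without day 4 replicate 1 (camera adjusted p = 0.756) and 0.39 without day 4 replicate 2, and the call was also lost without day 0 replicate 3 (adjusted p = 0.087). Of 15 pericyte and smooth muscle genes 0 passed, also adjusted over the list alone, and 2 had an unadjusted limma p under 0.05. Their median was 0.0047 (camera adjusted p = 0.774) and -0.020 after median centring. Of 6 platelet and megakaryocyte genes, Clec1b, which encodes the platelet receptor for podoplanin, rose by 1.05 ± 0.18 (SE), and adjusted over the list alone 2 were higher. The platelet median of -0.046 and the mean of 0.20 differed in sign, and the list did not pass (camera adjusted p = 0.492). The platelet median was -0.014 without day 4 replicate 1, and 2 of its genes were called without day 0 replicate 1 and 0 without any other single array.

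Among factors that support the thymus, Bmp4, an endothelial signal to thymic epithelium, stood at 7.20 ± 0.18 (SD, n = 3) at day 0 and 7.84 ± 0.42 (SD, n = 2) at day 4. Its day 4 arrays lay above all day 0 arrays, but the log2 change of 0.64 ± 0.20 (SE) did not pass the threshold (limma adjusted p = 0.144). Of 22 measured secreted factors and Notch ligands, 2 were higher and 1 lower, and adjusted over the list alone 3 were higher and 2 lower. Lif, a cytokine of the interleukin 6 family, rose from 3.42 ± 0.16 to 4.78 ± 0.20. It lay under the level filter on all day 0 arrays, so the size of its rise rests on background values. Selp, which encodes the leukocyte adhesion molecule P-selectin, rose by 0.94 ± 0.14, while Vegfc, a lymphatic growth factor, fell by 0.70. Neither Dll4, the Notch ligand needed for T cell commitment (0.13, adjusted p = 0.534), nor the alarmin gene Il33 (0.11, adjusted p = 0.876) passed. Il33 was 8.00 ± 0.38 (SD, n = 2) at day 4, and its change had the opposite sign without day 0 replicate 3 (-0.13) or without day 4 replicate 1 (-0.16). Kitl, which encodes stem cell factor, differed by 0.023 (adjusted p = 0.919) and by -0.0018 after median centring, while its 3 other probe sets gave 0.44 to 0.82. The list's median was 0.098 (camera adjusted p = 0.167), 0.059 without day 4 replicate 1 (adjusted p = 0.908) and 0.19 without day 4 replicate 2. Its calls numbered 2 higher and 1 lower without day 0 replicate 2, and 1 higher and 0 lower without day 0 replicate 1 or day 0 replicate 3. In the list of BMP and TGF-beta signalling, 1 of 25 members was higher, and 1 adjusted over the list alone. It was Inhbb, an activin subunit gene, at 1.11 ± 0.12 (SE), whose other probe set gave 0.31. That list's median was 0.085 (camera adjusted p = 0.0558), and it passed without day 0 replicate 3 (0.12, adjusted p = 0.0387) or day 4 replicate 1 (0.14, adjusted p = 0.0122). The median was closer to 0 without day 0 replicate 1 (0.039, adjusted p = 0.170) or day 4 replicate 2 (0.022, adjusted p = 0.220), and 0 BMP genes passed without day 0 replicate 3 or day 4 replicate 1.

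Of the 33 measured genes of endothelial identity, 0 passed the limma threshold, 0 did so adjusted over the list alone, and 4 had an unadjusted p under 0.05. The identity list's median was -0.085 (camera adjusted p = 0.333), and 0.094 without day 4 replicate 1, while without day 4 replicate 2 the list passed downward (-0.20, camera adjusted p = 0.0130). Of 17 venous genes, Selp was higher, and adjusted over the list alone 3 were. Venous calls numbered 2 without day 0 replicate 2, 1 without day 4 replicate 2 and 0 without any other single array. The venous median was 0.24 (camera adjusted p = 0.00106, adjusted p = 0.460 with an estimated correlation). The venous list shares 4 members with the list of inflammatory NF-kB targets, Selp among them, so the shifts of these lists are not separate results. Of 20 arterial genes, Cxcr4, the receptor for CXCL12, rose by 0.95 ± 0.17 (SE) and Vegfc fell. Adjusted over the list alone 1 was higher and 3 lower, and the arterial median was 0.025 (camera adjusted p = 0.809) and -0.064 without day 4 replicate 2. Over all genes 1 arterial gene was called without that array and 0 without any other single array. Aplnr, the apelin receptor gene, was the 1 lower gene of 13 on the capillary list, at -0.56 ± 0.10 (SE). Adjusted over the list alone 3 capillary genes were lower (median -0.12, camera adjusted p = 0.083), and the list passed without day 4 replicate 2 (-0.22, adjusted p = 0.0438) but not without day 4 replicate 1 (-0.059, adjusted p = 0.337). Of 24 genes of tip cells and sprouting, Cxcr4 and Angpt2, a ligand that loosens vessel walls, were higher. Angpt2 rose 1.68-fold, and Igfbp3, which binds insulin-like growth factors, fell by 0.75 on the log2 scale. Adjusted over the list alone, 4 tip cell genes were higher and 2 lower (median 0.094, camera adjusted p = 0.0811), and the list passed without day 0 replicate 3 (0.18, adjusted p = 0.0273) but had a median of 0.012 without day 0 replicate 1 (adjusted p = 0.317). Over all genes 5 tip cell genes were higher and 1 lower without day 4 replicate 2, and 0 passed without any other single array. Of 7 lymphatic genes 0 passed (2 at an unadjusted limma p under 0.05), and adjusted over the list alone 2 were lower (median -0.17, camera adjusted p = 0.250). The lymphatic median was -0.48 without day 4 replicate 1, -0.30 without day 0 replicate 3 and -0.088 without day 0 replicate 1. Of 23 basement membrane genes 3 were higher, and adjusted over the list alone 5 were higher and 2 lower (median 0.083, camera adjusted p = 0.0916). Higher calls in it numbered 0 without day 4 replicate 1 or day 0 replicate 3, 2 without day 0 replicate 1 and 1 without day 0 replicate 2 or day 4 replicate 2. The median was -0.011 without day 4 replicate 1 and 0.035 without day 0 replicate 1. P4ha1 and P4ha2, subunits of collagen prolyl hydroxylases, rose by 0.93 ± 0.12 and 0.82 ± 0.12 (SE).

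In the list of inflammatory NF-kB targets, 2 of 25 members were higher, and adjusted over the list alone 4 were higher and 1 lower. The 2 called over all genes were Selp and Tnfaip2, a gene induced by tumour necrosis factor, which rose by 0.78 ± 0.14 (SE). The list's median was 0.31 (limma camera adjusted p = 0.000243; adjusted p = 0.506 with an estimated correlation), and 0.22 without day 4 replicate 1, where the call was lost (adjusted p = 0.106). Single calls on it numbered 0 without day 0 replicate 1, day 0 replicate 3 or day 4 replicate 1, and 3 without day 4 replicate 2. Of 27 type I interferon response genes, Irf7, a transcription factor of that response, rose by 0.78 ± 0.11, and adjusted over the list alone 2 were higher. The median was 0.30 (camera adjusted p = 0.000112; adjusted p = 0.506 with an estimated correlation). The interferon shift rested on day 4 replicate 1, without which the median was 0.070 (camera adjusted p = 0.341). Single interferon genes numbered 4 without day 4 replicate 2 and 0 without any other single array. The list's mean level was 9.17 on day 4 replicate 1, 8.76 on day 4 replicate 2 and 8.64, 8.63 and 8.75 on the day 0 arrays. Psmb10, an immunoproteasome subunit gene, was the 1 lower gene of 12 in MHC class I presentation, at -0.51 ± 0.094 (SE). Adjusted over the list alone 3 of them were lower (median -0.21, camera adjusted p = 0.064), and the list passed without day 0 replicate 1 (-0.29, adjusted p = 0.0146) or day 0 replicate 2 (-0.24, adjusted p = 0.0496). Without day 0 replicate 3 its median was -0.11 (adjusted p = 0.231), and 0 of its genes were called without any single array. Of 8 MHC class II genes 0 passed (6 at an unadjusted limma p under 0.05), and adjusted over the list alone 2 were higher and 1 lower (median -0.74, camera adjusted p = 0.250). The class II median was -0.33 without day 4 replicate 2 and -1.15 without day 4 replicate 1, where the list passed (adjusted p = 0.0336). The myeloid list, which shares 1 member with the class II list, had a mean level of 7.24, 6.40 and 6.71 on the day 0 arrays and 7.75 and 7.46 on the day 4 arrays.

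In the list of apoptotic cell sensing, 2 of 21 members were higher, and 5 adjusted over the list alone. Gas6, a bridging ligand between dying cells and their receptors, rose from 9.26 ± 0.12 (SD, n = 3) to 10.56 ± 0.21 (SD, n = 2), with a limma adjusted p of 0.0124. Abca1, a lipid exporter gene, rose by 0.73 ± 0.13 (SE), with 0.38 on its other probe set. Rac1, a small GTPase gene, differed by -0.087 (adjusted p = 0.651), and by 0.25 on its other probe set. This list's median was 0.085 (camera adjusted p = 0.0295; adjusted p = 0.460 with an estimated correlation). The call was lost without day 0 replicate 2 (0.11, adjusted p = 0.0529), day 0 replicate 3 (0.063, adjusted p = 0.087) or day 4 replicate 2 (0.10, adjusted p = 0.061), and the median was 0.14 without day 0 replicate 1. Single calls on it numbered 1 without each day 0 array and 0 without day 4 replicate 1. In the list of zinc transport and sensing 1 of 17 members was higher, and 4 adjusted over the list alone (median 0.039, camera adjusted p = 0.144). The zinc median was 0.0037 without day 0 replicate 2, and calls on that list numbered 3 without day 4 replicate 2 and 0 without any other single array. The called gene was Mt1, which encodes a metal-binding metallothionein, at 0.71 ± 0.12 (SE), with 0.055 on its other probe set. Mt1 was also the 1 higher gene of 16 glucocorticoid targets, of which 2 were higher and 1 lower adjusted over the list alone (median 0.18, camera adjusted p = 0.0916). The glucocorticoid list passed without day 4 replicate 1 (0.24, adjusted p = 0.00511), while its median was 0.095 without day 4 replicate 2 (adjusted p = 0.216) or day 0 replicate 1 (adjusted p = 0.160). Its calls numbered 3 without day 4 replicate 2 and 0 without any other single array.

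No member of the remaining 4 lists passed the limma threshold over all genes. At an unadjusted p under 0.05 were 6 genes of cholesterol synthesis, 4 of endoplasmic reticulum stress, 3 of glycolysis and 6 of the immediate-early list. The cholesterol synthesis list had 2 of 16 members lower adjusted over the list alone. Its median was -0.27 (camera adjusted p = 0.000828; adjusted p = 0.431 with an estimated correlation), and 15 of the 16 values were below 0. For the 19 genes of endoplasmic reticulum stress the median was 0.21 (camera adjusted p = 0.000168; adjusted p = 0.460 with an estimated correlation), with 18 values above 0 and 0 members passing adjusted over the list alone. Glycolysis had 2 of 12 members higher adjusted over the list alone. Its median was 0.12 (camera adjusted p = 0.0295; adjusted p = 0.506 with an estimated correlation). It was 0.047 without day 4 replicate 1 (adjusted p = 0.211) and 0.22 without day 4 replicate 2, and the call was also lost without day 0 replicate 3 (adjusted p = 0.0796). The 24 immediate-early and dissociation stress genes had a median of 0.15 (camera adjusted p = 0.0295; adjusted p = 0.512 with an estimated correlation), with 1 higher adjusted over the list alone. The immediate-early median was 0.023 without day 4 replicate 1 (adjusted p = 0.223), 0.093 without day 0 replicate 1 (adjusted p = 0.182), 0.24 without day 4 replicate 2 and 0.020 with the covariate (adjusted p = 0.473). In all, 15 of 30 lists passed the camera threshold, 10 upward and 5 downward, 0 with an estimated correlation and 2 by fry (p53 targets and cholesterol synthesis). The estimated correlations were -0.012 for p53 targets and -0.034 for cholesterol synthesis, below the preset 0.01. For these lists the larger camera p with an estimated correlation therefore did not come from correlated members. Of the 15, 7 also passed without each single array, and 8 were lost without at least 1 of them. In the fit without day 4 replicate 1, no member was called on any list but those of p53 targets, mitosis, myeloid and erythroid cells. Higher calls appeared without day 4 replicate 2 for 2 genes each of DNA replication, endoplasmic reticulum stress and glycolysis and for 1 of endothelial identity.

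**Figure D3:**
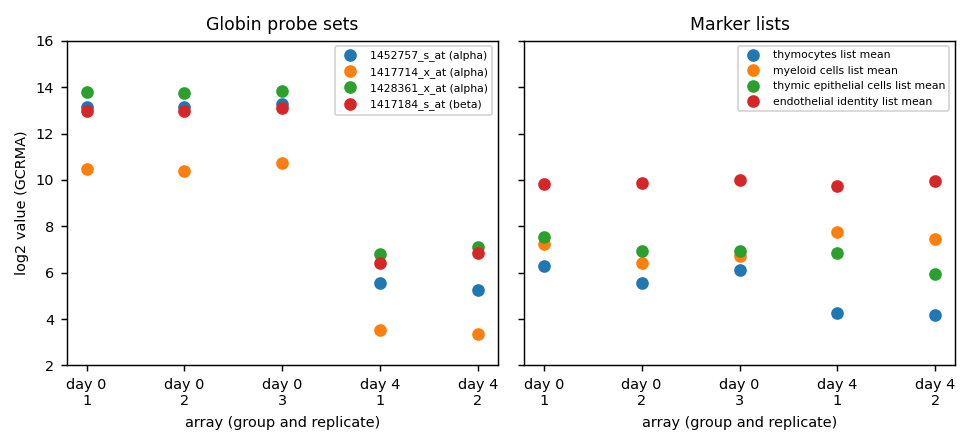
Left, GCRMA log2 value of 4 globin probe sets on each array, between 10.4 and 13.8 on the day 0 arrays and between 3.36 and 7.12 on the day 4 arrays. Right, mean log2 value of the members of 4 marker lists on each array, in which the thymocyte mean lies lower and the myeloid mean higher at day 4, and the endothelial identity list runs from 9.72 to 9.99.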

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

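The test over all probe sets and the list medians were planned, while the slopes, the use of Alas2, the globin gap, the share of the myeloid list and the reading of medians against explanations were chosen after the values were seen. Probe sets with several gene symbols, or with none listed, were left out of the comparison of genes, and 20 of them passed the threshold when all probe sets past the level filter were tested with limma. Of the 1197 such probe sets, 6 were higher and 14 lower at day 4. Several symbols were listed for 8 of the 20 and none for 12. The largest rise was that of probe set 1418949_at, from 6.63 ± 0.062 (SD, n = 3) to 10.45 ± 0.039 (SD, n = 2), a 14.2-fold change without a listed gene. Probe set 1416837_at, also unnamed here, rose by 2.45.

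The falls were led by 4 probe sets annotated to several globin genes, 3 of alpha-globin and 1 of beta-globin. They fell by 6.39 to 7.77 on the log2 scale, or 83.8-fold to 218-fold. The alpha-globin probe set 1452757_s_at went from 13.18 ± 0.068 (SD, n = 3) to 5.41 ± 0.20 (SD, n = 2), and the beta-globin probe set 1417184_s_at from 13.02 ± 0.082 to 6.63 ± 0.30. A general carry-over of thymic cells that was larger at day 0 cannot be decided here. The slope on the thymocyte list between arrays within a group had 2 residual degrees of freedom. It predicted a change of -0.54 ± 0.56 (SE) for the globin probe set farthest from the top of the scale, 1417714_x_at. The observed change was -7.08, and the myeloid list moved the other way (median 1.25). The prediction holds only if both groups carried over the same mix of cells, and irradiation depletes thymocytes. Fewer red cell precursors or reticulocytes in the sorted fraction may account for the fall, since Alas2, which could have stayed level, fell by 2.58. Epor (-0.27) and Ermap (0.18), the other erythroid genes past the level filter, did not pass the threshold. All probe sets of Slc4a1, Klf1, Rhag and Epb42 lay under the level filter on every array, day 0 included. The precursor account therefore rests on Alas2 alone. Mature red cells lack CD45, so the depletion would not remove them, while the VE-cadherin gate would. A difference in red cell removal between the preparations cannot be told apart from an effect of irradiation on blood formation. For 1417714_x_at alone, the gap between the lowest day 0 and the highest day 4 array was 6.84. The labels do not say which arrays were prepared together.

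Several genes known from macrophages, Cd163 among them, rose at day 4. Signal of other cells did not rise for every kind, since the thymocyte list had a median of -1.67. Irradiation depletes thymocytes, so that fall cannot decide whether carry-over of the remaining cells was larger at day 4. More macrophages, or more of their RNA, in the sorted fraction may account for the rise, though the CD45 depletion and gate should have removed them. Of 18 measured members of the fixed myeloid list, 88.9% had changes above 0, among them the abundant Lyz2 (8.63 to 10.37) and Ctss (8.43 to 10.20). Of the 18, however, only 1 passed the threshold upward and 2 passed downward, Lyz2 (adjusted p = 0.0924) and Ctss (adjusted p = 0.0695) did not pass, Ptprc, the CD45 gene, counted at a change of 0.0049 (-0.015 with quantile normalization), and the list had an adjusted p = 0.506 with an estimated correlation. Higher expression by the endothelial cells themselves cannot be told apart from this, because a pooled fraction does not separate cells and the endothelial identity list differed by a median of -0.085.

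Of 22 mitosis genes 11 fell, beside 7 of 11 genes of thymocytes, cells that the CD45 gate should have removed. Loss of carried-over dividing thymocytes stays open: the slope between arrays of one group predicted a change of -0.79 ± 0.35 (SE) in the mean of the mitosis list, against -0.91 observed, with 2 residual degrees of freedom. None of the 11 thymocyte genes measured is held by another list, and their most abundant members at day 0 were Satb1 (7.18), Dntt (7.12) and Rag1 (7.11). A fall in dividing endothelial cells stays open, since the part left was -0.12 ± 0.37, too imprecise to decide. Within groups the mitosis list also followed the myeloid list (slope 0.44 ± 0.044), which predicted a rise of 0.36 ± 0.037 and left -1.27 ± 0.045, so the slope is not specific to thymocytes, and with the covariate averaging both lists, which moved in opposite directions, the mitosis median was -0.67.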

How the results depend on the processing

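The covariate for other cells was chosen after the values were seen; the other settings were planned. With 2 day 4 arrays, the fits without one of them assume that the lone array varies like the others. Of 255 called genes (134 higher, 121 lower), 86 (49 and 37) passed with array weights, 418 (206 and 212) with an intensity trend and robust fitting, and 102 (76 and 26) with the covariate. Adjusted p under 0.01 left 22 (14 and 8), under 0.1 gave 673 (338 and 335), and a 2-fold minimum left 129 (68 and 61). Leaving out each array gave 10 to 317 genes, 6 to 211 higher and 4 to 106 lower. Counts were 153 (98 and 55) without day 0 replicate 1, 162 (60 and 102) without day 0 replicate 2, 40 (25 and 15) without day 0 replicate 3, 10 (6 and 4) without day 4 replicate 1 and 317 (211 and 106) without day 4 replicate 2. Quantile normalization gave 260, median centring 253, no filter 225, a filter at 6 268, the mean of probe sets 239 and all probe sets 210. No called gene had the opposite sign under any setting for which shared calls were counted. Where fewer arrays or a stricter threshold did not itself lower a count, the cause was not tested.

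The replicate numbers are shared by 2 pairs with no stated common origin. Deviations from the group means correlated at 0.16 for number 1 and 0.078 for number 2. The deviations of 2 day 4 arrays mirror each other, so these 2 values are not independent. Day 4 number 1 with day 0 number 2 gave -0.078, the value for number 2 with its sign changed. The correlations therefore cannot decide whether equal numbers share an origin. With the replicate block, 481 genes passed (257 higher, 224 lower). Day 0 replicate 3 shares its number with no day 4 array, so the block fits it exactly. The list medians therefore equalled those without that array, 0.57 for p53 targets and -1.40 for thymocytes. The fit left 1 residual degree of freedom, so its count rests on little information about the spread.

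Of 30 lists, 15 passed by camera, 13 to 15 without each array, 0 with an estimated correlation and 2 by fry. The lists differed: 7 of the 15 passed without each array (p53 targets, mitosis, thymocytes, myeloid cells, venous endothelium, cholesterol synthesis and endoplasmic reticulum stress). Without day 4 replicate 1, 5 were lost (NF-kB targets, interferon response, fibroblasts, glycolysis and immediate-early genes) and 3 gained. Without day 4 replicate 2, 3 were lost (thymic epithelium, DNA replication and apoptotic cell sensing) and 2 gained. With an estimated correlation the adjusted p was 0.109 for p53 targets (median 0.55), 0.460 for mitosis (-0.86), 0.460 for thymocytes (-1.67) and 0.506 for myeloid cells (1.25). By fry it was 0.0618 for mitosis and for thymocytes and 0.219 for myeloid cells, at the same medians. Without each array the medians ran from 0.53 to 0.62 for p53 targets, -0.96 to -0.70 for mitosis, -1.90 to -1.40 for thymocytes and 1.05 to 1.46 for myeloid cells. The mean correlation within groups exceeded that between them by 0.0173, by 0.0081 with no filter, by 0.0285 with a filter at 6 and by 0.0146 to 0.0220 without each array.

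Medians near 0 changed sign, and the cause was not tested; ranges are over the fits without each array. Pericytes (-0.058 to 0.038) went to -0.020 with median centring, -0.058 with the replicate block or without day 0 replicate 3, and -0.013 without day 4 replicate 1. Platelets went to 0.17 without a filter. Arterial genes (-0.064 to 0.068) went to -0.020 with a filter at 6, -0.064 without day 4 replicate 2 and -0.028 with the covariate. Endothelial identity (-0.20 to 0.094) went to 0.094, and basement membrane (-0.011 to 0.097) and fibroblasts (-0.011 to 0.39) to -0.011 each, without day 4 replicate 1. With the covariate, basement membrane went to -0.026 and tip cells to -0.023.

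Of the 48 called genes among the 57 named, 0 changed direction, and 6 (Cd163, Phlda3, Ccng1, Lif, S100a8 and Alas2) passed in every fit that tested them. Cd163 and Lif lay under the level filter on all day 0 arrays, so the fits without a day 4 array did not test them. Calls were lost for 41 named genes without day 4 replicate 1, 35 without day 0 replicate 3, 18 without day 4 replicate 2, 14 without day 0 replicate 2, 13 without day 0 replicate 1, 23 with array weights and 22 with the covariate. Uncalled genes changed sign as follows, and the cause was not tested. Ptprc (-0.22 to 0.17) went to -0.015 with quantile normalization, -0.020 with median centring, -0.22 without day 0 replicate 2 and -0.15 without day 4 replicate 1. Kitl (-0.081 to 0.13) went to -0.0018 with median centring, -5.0e-05 with the replicate block or without day 0 replicate 3, -0.081 without day 4 replicate 2 and -0.016 with the covariate. Rac1 (-0.18 to 0.0045) went to 0.080 with the mean of probe sets and 0.0045 without day 4 replicate 1. Il33 (-0.16 to 0.42) went to -0.13 with the replicate block or without day 0 replicate 3 and -0.16 without day 4 replicate 1. Pecam1 (-0.051 to 0.33) went to -0.051 without day 4 replicate 2, and Epcam (-1.23 to 0.27) to 0.27 without it and 0.12 with the covariate. Low signal limits 42 lower genes, whose day 4 mean lay under the level filter, and 16 higher ones at day 0.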

Other observations

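The lists and slopes in this part were chosen after the values were seen, while calls over all genes come from the planned comparison. Genes outside the fixed rule were picked from their values. A list of clock genes was written after the rise of Per2 was seen. Of its 10 measured genes of the Per and Dbp phase of the circadian cycle, 9 had changes above 0 and 2 passed the limma threshold over all genes, 9 adjusted over the list alone. Per2, a repressor in the clock, rose by 1.46 ± 0.23 (SE) and Nr1d2, which encodes the nuclear receptor REV-ERB beta, by 0.75 ± 0.13. Dbp differed by 1.09 (adjusted p = 0.118). The list's median was 0.61, with no list test given because its members were chosen around Per2. Of the opposite phase 4 genes were measured, too few for a list test, with a median of -0.20, and 0 passed, also adjusted over the list alone. Arntl, the clock activator BMAL1, differed by -0.99 (adjusted p = 0.233). The labels give no hour of harvest.

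Antigens of other tissues, which medullary thymic epithelium is known to express, were examined because Csn2 fell. Of 16 measured members of a list written without the genes already seen to fall, 14 had changes below 0 and 0 passed the limma threshold (8 at an unadjusted p under 0.05), with 6 lower adjusted over the list alone. The median was -0.66 (camera adjusted p = 0.000187, adjusted p = 0.280 with an estimated correlation, fry adjusted p = 0.138). These p-values were adjusted only over the lists added after the values were seen, some of which hold genes already seen to change. The list's mean level was 5.21, 4.23 and 5.15 on the day 0 arrays and 3.90 and 3.92 on the day 4 arrays, so day 0 replicate 2 lay near the day 4 arrays, which were under the level filter. Fezf2, a regulator of such antigens, fell by 1.17 (limma adjusted p = 0.0362), and Aire, another one, differed by -1.18 (adjusted p = 0.0573). Hypoxia response genes, listed after Hilpda, P4ha1 and Hk2 were seen, had 3 of 23 measured members higher, and 8 adjusted over the list alone, with a median of 0.18. Besides P4ha1 and P4ha2 this was Hilpda, a lipid droplet protein, which rose by 1.48 ± 0.15 (SE).

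Of 38 measured macrophage genes on a list written after the largest rises were seen, 36 had changes above 0, 15 of them past the threshold over all genes and 35 adjusted over the list alone. Their median was 1.37, which restates those rises because genes already seen are among them. The neutrophil list, written after S100a8 and S100a9 were seen, had 3 of 6 measured members lower, over all genes and adjusted over the list alone, which were S100a8, S100a9 and Camp (-1.11). The median of that list was -0.55. Glycam1, a mucin of high endothelial venules, had a value of 10.95 ± 0.88 (SD, n = 3) at day 0 and 5.77 ± 2.7 (SD, n = 2) at day 4, a change of -5.18 that did not pass (limma adjusted p = 0.0633). The within-group slopes that were computed for the mitosis list were also computed for p53 targets, with 2 residual degrees of freedom. The thymocyte slope predicted -0.016 ± 0.092 (SE) and the myeloid slope -0.015 ± 0.035, against 0.67 observed. These predictions hold only if both groups carried over the same mix of cells in the same state. They cannot decide whether carried-over irradiated cells held part of the rise.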
